A study of Mus musculus with 8 samples.

How the data were processed

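RNA of naive B cells isolated from the spleens of C57BL/6 mice was sequenced from 8 libraries in 4 groups of 2. These were WT without a tumor, WT with a pancreatic tumor, mice whose B cells lack Ebi3 (EBi3KO) without a tumor, and EBi3KO with a tumor. The nontumor groups are those whose tumor status is labelled WT, a reading that the labels do not spell out and on which every tumor comparison rests. Per the submitters' processing notes, reads were quantified with Salmon against mm10 and normalized with DESeq2, whose versions are not given in the sources used here. The deposited values are normalized counts (signal), written by the authors as 1 value per gene symbol and library. Each library's values were divided by the step between them, and 100% were then whole reads within a tolerance of 0.01, so that reads per gene and the size factor of each library could be recovered. The recovered depth was 26065124 and 21762499 reads for WT nontumor replicates 1 and 2, 27402047 and 27176751 for WT tumor, 21291892 and 22366598 for EBi3KO nontumor, and 28297319 and 26846836 for EBi3KO tumor.

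The table held 23302 entries, of which 5065 were at 0 in every library. The 13011 genes with a mean of at least 10 over the 8 libraries were tested. Counts were taken to log2 after adding 1, and 1 model with a mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3, with the prior variance following the mean (4 residual and 4.64 prior degrees of freedom). Its tests are two-sided. P-values were adjusted by Benjamini-Hochberg over all tested genes within each comparison, and genes below 0.05 are called higher or lower. Errors printed with a log2 difference are limma's standard errors, and means of normalized counts are given ± SD over the 2 libraries of a group. A fold against a group with 0 reads in both libraries was computed against a floor of 3 reads per library. Such floors and intervals cover counting error only. The labels do not say whether the 2 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries.

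There were 5 comparisons: tumor against nontumor within WT and within EBi3KO, EBi3KO against WT within nontumor and within tumor mice, and the interaction, which is the tumor effect in EBi3KO minus that in WT. With groups of 2, other splits of the libraries could not be compared. The WT tumor libraries differ from the other groups in sex and in the prefix of their titles. The tumor effect in WT, the genotype effect in tumor mice and the interaction therefore carry both differences, while the tumor effect in EBi3KO and the genotype effect in nontumor mice carry neither.

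Before the data were examined, 37 gene lists were written, 23 of them on B cell programs and metabolism and the others on RNA quality, sex and markers of other cell types. Lists with at least 5 tested members were tested with camera in limma at a preset correlation between genes of 0.01, and again with the correlation estimated for each list, adjusted over lists within each comparison. The switched immunoglobulin constant genes and the mitochondrially encoded genes had 0 members in the table, which also holds no immunoglobulin V, D or J segments. Under an older symbol 4 list members were found: Jchain as Igj, Adgre1 as Emr1, Hbb-bs as Beta-s and Rigi as Ddx58. Date names stood in place of gene symbols in 27 entries, none of which is named here. Adjustment over the list alone used the members of that list only.

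Named genes follow a fixed rule. In every comparison Ebi3, Il12a, Bcl6, Pax5, Prdm1, Irf4, Xbp1 and Stat3 are given. Of the genes past the threshold whose 2 libraries in a group all lie above the 2 of the other (a condition not set for the interaction) and whose higher group mean is at least 50, the 10 largest rises and the 10 largest falls may be named. Passed over were gene models named Gm, names ending in Rik, pseudogenes and antigen receptor segments. The 4 members of each list with the smallest p complete the rule, and with fewer than 20 genes past the threshold the 10 with the smallest p are given as not past it. Some genes that meet this rule are not reported here.

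Alternatives were a pseudocount of 5 or 0.1, no filter or a mean of at least 50, quantile or upper-quartile scaling, moderation without the trend or made robust, and array weights. Others were a fit of the compared libraries alone, each library left out in turn, the title number as a replicate block, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. After the data had been seen, 3 more were added: removal of each library's trend on transcript length and GC content, the EBi3KO tumor libraries averaged as 1 sample, and chromosomes X and Y left out. The fits were tested on simulated data with 200 of 13011 genes changed. At 2-fold, limma recovered 61.2% in the tumor effect in WT, 65.7% in that in EBi3KO and 74.6% in the genotype effect in nontumor mice. Of the calls, 9.3%, 4.62% and 6.76% were false. With a trend of 0.5 on the log2 scale per doubling of transcript length added to the simulated WT tumor libraries, 96.7% were false (4551 genes), and 5.63% once the trend was removed. Transcript length and GC content came from the mm10 annotation for 98.9% of tested genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.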

Results

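Gene expression was measured by RNA sequencing in naive B cells from mouse spleens, in WT mice and in mice whose B cells lack Ebi3 (EBi3KO), each with and without a pancreatic tumor. Each of the 4 groups held 2 libraries. Depth was 26065124 and 21762499 reads in WT nontumor, 27402047 and 27176751 in WT tumor, 21291892 and 22366598 in EBi3KO nontumor, and 28297319 and 26846836 in EBi3KO tumor. The first principal component held 83.2% of the variance and ran from the nontumor libraries of both genotypes (-76.36 to -38.81) through EBi3KO tumor (10.87 and 11.77) to WT tumor (95.61 and 109.1). Xist, which silences the inactive X chromosome, averaged 22974 ± 4549 normalized counts in WT tumor against 6.22 ± 0.898 in WT nontumor, 10.2 ± 3.63 in EBi3KO nontumor and 16.5 ± 2.55 in EBi3KO tumor (n = 2 each). The Y-linked Eif2s3y, Kdm5d and Uty had 0 reads in both WT tumor libraries and were expressed in every other library. The WT tumor libraries therefore carry a female pattern and all others a male one. Only the WT tumor titles begin with IV, where the others begin with OT.

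The tumor effect in WT asks how naive B cells of WT mice differ when a pancreatic tumor is present. Ebi3, the subunit shared by IL-35 and IL-27, rose from 9.96 ± 1.44 to 182 ± 26.4 normalized counts (n = 2 each, 16.7-fold with 1 added to each value, log2 difference 4.06, SE 0.303, limma adjusted p = 4.77e-06). Bach2, a repressor of plasma cell differentiation, went from 1853 ± 230 to 8590 ± 635 (log2 difference 2.22, adjusted p = 3.8e-07). Igj, the joining chain of secreted IgM and IgA, fell from 26686 ± 3052 to 3522 ± 533 (-2.92, SE 0.119, adjusted p = 2.99e-07). 

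Of the genes fixed for all comparisons, Bcl6, the repressor that drives the germinal center, rose by 0.72 on the log2 scale (adjusted p = 2.91e-05) and Pax5, which maintains B cell identity, by 0.48 (0.00727). Il12a, the other chain of IL-35, rose by 0.60 (0.034), a call that ended in 9 of 24 alternatives. Irf4 rose by 1.05 (0.000536) and Stat3 by 0.39 (0.000848), while Xbp1, the transcription factor of secretory cells, fell by 0.43 (0.00162). These 3 calls ended once the trend on transcript length and GC content was removed, where Stat3 stood at -0.02 and Xbp1 at 0.06. Prdm1, which commits B cells to the plasma cell fate, differed by 0.05 (0.768).

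**Figure D1:**
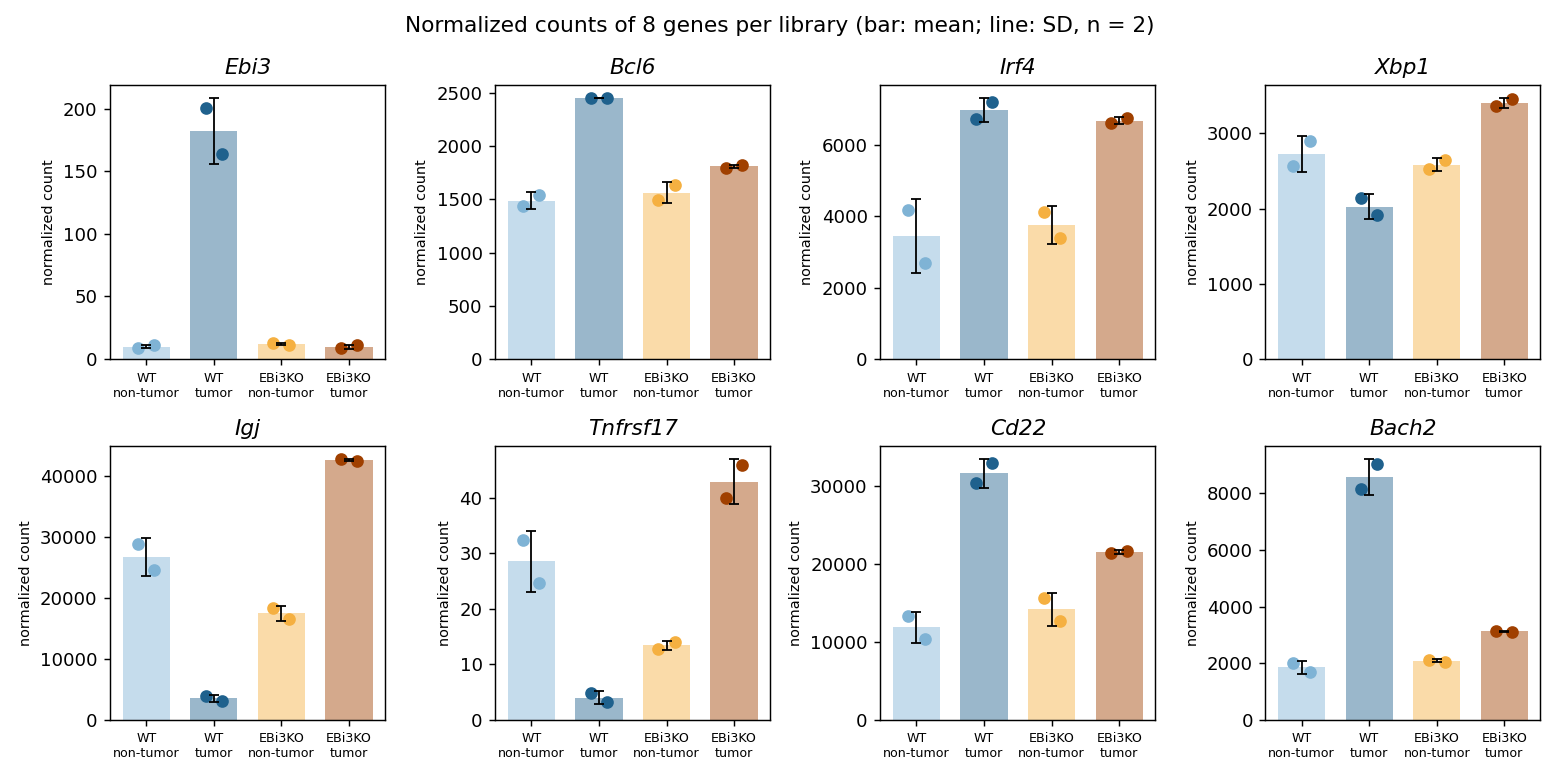
Normalized counts of 8 genes in the 4 groups: bars are means, lines ± SD and points the 2 libraries of each group. Ebi3 stands at 182 in WT tumor and at 9.85 to 12.1 in the other groups, and Igj at 3522 in WT tumor against 42591 in EBi3KO tumor.

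Among 16 tested B cell identity genes 10 rose, 3 fell and 3 did not pass, with Ebf1 (log2 difference 1.81), Cd22 (1.43) and Fcer2a (0.71) among those that rose. The list as a whole was not past the threshold (median 0.43, camera adjusted p = 0.119). It was past in 2 of 20 alternatives, among them removal of the length and GC trend (12 rose, 1 fell, median 0.36, camera adjusted p = 0.0135). Quiescence and naive-state genes were past the threshold (9 of 13 rose, 1 fell, median 0.62, camera adjusted p = 0.0232, but adjusted p = 0.614 with an estimated correlation). Among them Foxp1 stood at 1.33, Cxcr5, the receptor that guides B cells to follicles, at 0.62 and Foxo1 at 0.95. Foxo1 turned to -0.41 once the length and GC trend was removed, and the call of the list ended, at a median of 0.40. Of 14 genes of chemokine receptors and homing 8 rose and 0 fell (median 0.42, camera adjusted p = 0.0427, but adjusted p = 0.614 with an estimated correlation), led by the integrin chain Itga4 (2.05, from 3376 ± 760 to 13890 ± 1741) and Ccr6 (1.38). This list lost its call in 6 of 20 alternatives. Of the IL-35 receptor and STAT genes 8 of 14 rose and 0 fell, with Jak1 at 0.76 and Il6st, the signal-transducing receptor of the IL-6 family, at 0.78 (camera adjusted p = 0.131). After removal of the length and GC trend 4 of the 14 rose and 2 fell, at a median of -0.008 in place of 0.37. Regulatory B cell genes went both ways, 7 of 18 up and 6 down. The checkpoint ligand Cd274 rose by 1.06, and Lag3 fell by 3.33, Cd9 by 1.68 and the ectonucleotidase Entpd1 by 1.15 (camera adjusted p = 0.838, direction down, while the median was 0.15).

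The plasma cell program split as well, with 5 of 16 members up and 8 down (median -0.33, camera adjusted p = 0.446). After removal of the length and GC trend 4 rose and 7 fell, at a median of -0.02. Mzb1 fell by 1.63 and Prdx4, an oxidase of disulfide formation, by 1.75, together with Tnfrsf17, the plasma cell survival receptor BCMA (-2.58, from 28.6 ± 5.46 to 3.96 ± 1.14), while Slamf7 rose by 1.03. Of 6 plasma cell markers 1 rose and 3 fell (camera adjusted p = 0.444). In the germinal centre program 2 rose, 3 fell and 8 did not pass (0.615), with Mybl1 at 2.20 and Plxnb2 at -1.66. Marginal zone genes stood at 4 up and 4 down of 13 (0.81). Dtx1, a Notch target, fell by 1.08, and Notch2 stood at 1.101, which turned to -0.28 after removal of the length and GC trend. B-1 genes stood at 2 up and 1 down of 9 (0.689), with Bhlhe41 at 0.55, a call that ended after that removal.

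Of 17 immediate early genes 10 fell and 1 rose (median -0.90, camera adjusted p = 0.0807), with the co-stimulatory ligand Cd86 at -1.61, Egr2 at -1.35 and Egr3 at 1.20. Type I interferon genes stood at 9 up and 8 down of 23 (0.615), the RNA sensor Ddx58 rising by 1.19 and the virion tether Bst2 falling by 1.47. Interferon gamma genes stood at 8 up and 7 down of 17 (0.928), with Gbp4 at 1.93 and the immunoproteasome subunit Psmb9 at -1.28. In MHC class II presentation Ciita, the master regulator of the pathway, rose by 1.52 while H2-DMa, which loads peptide, fell by 1.16 and the protease Ctss by 1.11. In all 8 of its 12 members fell and 2 rose (0.104). Co-stimulation genes stood at 3 up and 3 down of 8 (0.838), with Cd40 at -0.49, which turned to 0.04 after the length and GC trend was removed. NF-kB targets stood at 3 up and 6 down of 14 (0.615), with Bcl2a1d at -2.02. BAFF and survival genes stood at 4 up and 4 down of 10 (0.96, direction up at a median of -0.10), with the BAFF receptor Tnfrsf13c at 0.70 and the anti-apoptotic Mcl1 at 0.51.

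Of 20 cell cycle genes 18 fell and 1 rose (median -1.41, camera adjusted p = 2.08e-05, but adjusted p = 0.614 with an estimated correlation). Rrm2, the ribonucleotide reductase subunit, went from 5262 ± 482 to 544 ± 32.1. All 12 erythroid genes fell in the same comparison (median -3.92), and which cells the cell cycle transcripts came from was not tested. All 82 tested cytosolic ribosomal proteins fell (median -1.81, 8.37e-20), as did 73 of 77 oxidative phosphorylation genes (-1.68, 6.93e-17) and 12 of 15 glycolysis genes (-0.85, 0.0143). These 3 lists had an adjusted p = 0.614 with an estimated correlation. Rps12 stood at -2.39, Atp5e at -2.57 and Ldha at -1.28. The share of reads on ribosomal proteins went from 23.68 ± 0.339% to 9.545 ± 1.01% (n = 2 each). The ribosomal median moved to -0.65 under quantile normalization. Removal of the length and GC trend took it to -1.18, that of oxidative phosphorylation to -1.001 and that of glycolysis, whose call ended, to -0.47. Of 8 heat shock genes 6 fell (median -1.05, 0.0299, but adjusted p = 0.614 with an estimated correlation, call ended in 4 of 20 alternatives), with Hspa1a at -8.37 and Hspa8 at -0.73, which turned to 0.63 under quantile normalization. Histone genes stood at 2 up and 12 down of 17 (0.123), and unfolded protein response genes at 4 up and 7 down of 15 (0.444), with Sdf2l1 at -1.75 and Sel1l at 0.94 (-0.08 after removal of the trend). Cholesterol synthesis genes stood at 7 up and 4 down of 15 (0.446).

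In the same libraries all 14 monocyte and macrophage genes (median -3.13, camera adjusted p = 7.67e-07), all 12 erythroid genes (-3.92, 3.77e-06) and all 8 platelet genes (-2.60, 0.00741) fell, each list with an adjusted p = 0.614 with an estimated correlation. The complement gene C1qc went from 12892 ± 1891 to 582 ± 90.5. So did 11 of 12 granulocyte genes (-4.11, 0.00337), 7 of 8 NK genes (-1.65, 0.0232) and 8 of 10 dendritic cell genes (-1.65, 0.0294), again at adjusted p = 0.614 with an estimated correlation. T cell genes (8 of 12 fell, 0.131) and stroma (7 of 9 fell, 0.123) were not past the threshold as lists. Monocyte and macrophage markers went from 0.3762 ± 0.0168% to 0.0485 ± 0.00451% of the reads, and erythroid markers from 0.679 ± 0.0351% to 0.1054 ± 0.0218%. Of 5 pancreas and epithelium genes 2 rose and 3 fell (0.515). Pnlip, the pancreatic lipase, went from 0 reads to 12.3 ± 0.642 normalized counts (at least 3.28-fold), and Cela1 fell from 1803 ± 210 to 76.7 ± 17.3. Of the sex-linked list 4 of 5 fell (camera adjusted p = 0.0427, but adjusted p = 0.614 with an estimated correlation, past in 12 of 19 alternatives) at a median of -9, or -7.81 with its 3 genes at 0 set to their bound.

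Among the largest rises beside Xist were H2-Q6, a class I gene of a family of close paralogs (0 reads to 1551 ± 789, at least 415-fold), the zinc finger gene Zbed6 (5.33), Vasn (5.27) and the complement regulator Daf2 (4.81). Among the largest falls were Eif2s3y (at least 1060-fold lower), Uty (at least 225-fold), the amino acid transporter Slc38a5 (-6.81) and the sphingosine kinase Sphk1 (-6.51). In all 10378 of 13011 genes (79.76%) were past the threshold in limma, 5157 higher and 5221 lower, and 5490 of them differed by at least 2-fold. Adjusted over the list alone, the counts of the lists were the same as over all genes except for B cell identity (10 rose, 4 fell), B-1 genes (1 rose, 0 fell), type I interferon (9 and 7) and interferon gamma (8 and 8). Across genes, which are not independent replicates, the log2 difference rose with transcript length (Spearman's rho 0.358), and libraries of the same WT group also differed along length (rho -0.262 in nontumor and 0.274 in tumor). In simulated libraries with 200 changed genes and a length trend added, 96.7% of the calls of this comparison were false. That share depends on the small number of changes set in advance and does not estimate the false calls in the data. Of the 10378 genes called here, 8596 were also past the threshold after removal of the length and GC trend, 373 of them in the opposite direction.

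**Figure D2:**
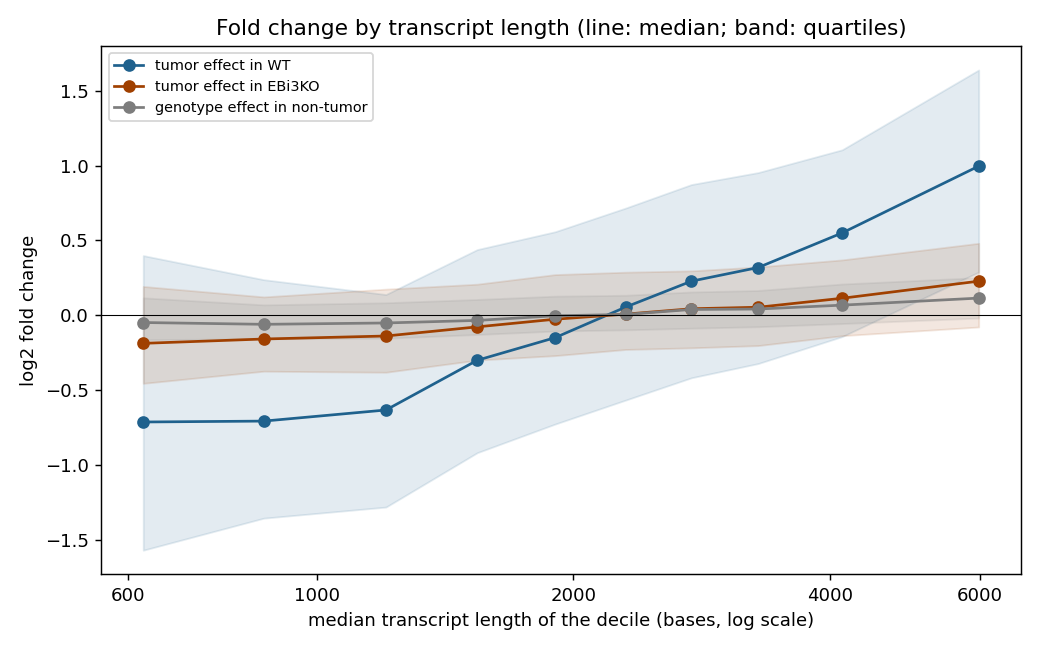
Median log2 difference of the genes in each of 10 equal bins of transcript length, for the tumor effects in WT and EBi3KO and the genotype effect in nontumor mice. The genotype effect in tumor mice and the interaction are not drawn. In the tumor effect in WT the medians run from -0.71 in the shortest genes to 0.996 in the longest.

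The tumor effect in EBi3KO asks the same of B cells without Ebi3, in libraries of 1 sex and title prefix. Here Igj rose, from 17430 ± 1258 to 42591 ± 203 normalized counts (n = 2 each, log2 difference 1.29, SE 0.119, adjusted p = 0.000227), and all 6 tested plasma cell markers rose (median 0.71, camera adjusted p = 0.000387, but adjusted p = 0.403 with an estimated correlation). The chemokine receptor Cxcr4 rose from 7635 ± 1014 to 16542 ± 343 (1.12, adjusted p = 0.000245), Tsc22d3, a glucocorticoid-induced gene, from 13848 ± 2997 to 32418 ± 139 (1.24, 0.00156) and the activation marker Cd69 from 3182 ± 824 to 7948 ± 10.1 (1.34, 0.00202). Every tested cell cycle gene fell (20 of 20, median -1.12, camera adjusted p = 4.89e-15, but adjusted p = 0.403 with an estimated correlation), Rrm2 from 5637 ± 545 to 959 ± 10.9. All 12 erythroid genes fell in the same comparison (median -2.76). Which cells the cell cycle transcripts came from was not tested. Ebi3 itself stood at 12.1 ± 0.931 and 9.85 ± 1.63 (-0.28, adjusted p = 0.492).

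Of the other fixed genes, Prdm1 rose by 0.56 (adjusted p = 0.0302), Irf4 by 0.84 (0.012), Xbp1 by 0.40 (0.0131) and Stat3 by 0.32 (0.0132), while Bcl6 (0.21, 0.0583), Pax5 (0.15, 0.379) and Il12a (-0.10, 0.754) were not past the threshold. The calls of Irf4, Xbp1 and Stat3 ended without EBi3KO nontumor replicate 2, without either EBi3KO tumor library and with those averaged as 1 sample. That of Prdm1 ended in these and 4 further alternatives. In the plasma cell program 9 of 16 genes rose and 1 fell (median 0.39, camera adjusted p = 0.00959, but adjusted p = 0.475 with an estimated correlation). Tnfrsf17 went from 13.4 ± 0.87 to 42.9 ± 4.11 (1.61), and Derl3, of protein export from the endoplasmic reticulum, rose by 0.85 and the plasma cell surface proteoglycan Sdc1 by 0.54. The unfolded protein response had 6 of 15 up and 0 down (0.0739), with Dnajb9 at 0.57 and Atf4 at 0.56. Plasma cell markers took 0.07408 ± 0.00671% of the reads without and 0.1906 ± 0.000707% with a tumor.

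Of 13 quiescence and naive-state genes 6 rose, 0 fell and 7 did not pass (median 0.29, camera adjusted p = 0.00663, but adjusted p = 0.536 with an estimated correlation). Bach2 rose by 0.58 (adjusted p = 0.00406), Btg1, which restrains proliferation, by 0.45 and Satb1 by 0.50. The medians of this list without EBi3KO nontumor replicate 2 and after removal of the length and GC trend were lower, at 0.17 and 0.10. Of 16 identity genes 3 rose and 0 fell (0.129), with Cd22 at 0.61. The identity list was past the threshold in 2 of 20 alternatives, among them removal of the length and GC trend (5 rose, 0 fell, median 0.12, camera adjusted p = 0.0215). IL-35 receptor and STAT genes stood at 3 up of 14 (median 0.21, 0.0431, but adjusted p = 0.536 with an estimated correlation, call ended in 5 of 20 alternatives, median 0.11 after removal of that trend), with Socs3, the feedback inhibitor of STAT3, at 0.80 and the kinase Pim1 at 0.41. Chemokine receptors and homing stood at 2 up and 1 down of 14 (median 0.23, 0.0354, but adjusted p = 0.559 with an estimated correlation, call ended in 3 of 20 alternatives, median 0.14 after removal of that trend), with Gpr183, which positions B cells in the follicle, at 0.51. Regulatory B cell genes had 6 up and 2 down of 18 (0.447). The ectonucleotidase Nt5e rose by 1.57, Fcgr2b, the inhibitory Fc receptor, by 0.41 and Ctla4 by 2.90, while Lag3 fell by 1.19 (0.000365).

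Among the remaining B cell lists, 5 of 13 marginal zone genes fell and 1 rose (0.172), Dtx1 by 0.57 and Cd36 by 0.62. Of 17 immediate early genes 5 rose and 2 fell (0.317), with Nr4a1, an early target of the antigen receptor, at 1.45 and Cd86 at -0.66. Of 23 type I interferon genes 7 fell and 2 rose (0.536), with the antiviral gene Rsad2 at -1.43 and Isg15 at -0.86. Of 17 interferon gamma genes 4 rose (0.366), with Nlrc5, the regulator of MHC class I, at 1.05. MHC class II genes stood at 3 up and 1 down of 12 (0.971, direction up, median -0.10, mean -0.01), with Ciita at 0.50. Co-stimulation genes stood at 1 down of 8 (0.554), NF-kB targets at 1 up of 14 (0.665), and BAFF and survival genes at 3 up and 1 down of 10 (0.69, direction up, median -0.06), with Tnfrsf13c at 0.35. There were germinal centre genes at 1 down of 13 (0.613), B-1 genes at 1 up of 9 (0.251) and cholesterol synthesis genes at 3 up and 1 down of 15 (0.29), with Plxnb2 at -0.63.

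Ribosomal proteins (70 of 82 fell, median -0.44, camera adjusted p = 8.44e-16), oxidative phosphorylation (66 of 77 fell and 1 rose, -0.46, 1.04e-15) and heat shock genes (7 of 8 fell, -0.84, 0.000113) fell in EBi3KO also. Each of the 3 lists had an adjusted p = 0.536 with an estimated correlation. Rps12 stood at -0.78, Atp5e at -0.68 and Hspe1 at -0.59. The ribosomal median was -0.08 under quantile normalization and -0.29 after removal of the length and GC trend, and the heat shock median was -0.47 without EBi3KO nontumor replicate 1. Hspa1a went from 19641 ± 22400 to 69.2 ± 3.19. Of 15 glycolysis genes 4 fell (median -0.30, 0.0136, but adjusted p = 0.559 with an estimated correlation, call ended in 2 of 20 alternatives, median -0.18 under quantile normalization), with Gpi1 at -0.38, and histones stood at 1 up and 1 down of 17 (0.823). Of the other-cell markers, erythroid genes (12 of 12 fell, median -2.76, 2.59e-14), monocyte and macrophage genes (11 of 14, -0.88, 4.9e-06), granulocyte genes (8 of 12, -2.39, 0.000144) and stroma (7 of 9, -2.39, 0.0174, call ended in 2 of 19 alternatives) fell. The p of these lists with an estimated correlation was adjusted p = 0.253 for erythroid genes, adjusted p = 0.403 for stroma and adjusted p = 0.536 for the others. C1qc went from 11726 ± 1459 to 5214 ± 38.3. Dendritic cells (4 of 10 fell, 0.0868), T cells (1 up, 1 down of 12, 0.0739), NK cells (0 of 8, 0.232), platelets (1 up, 1 down of 8, 0.879), pancreas and epithelium (1 up, 1 down of 5, 0.879, direction down, mean 0.65) and sex-linked genes (0 of 5, 0.2) were not past the threshold. Pnlip went from 0 reads to 38 ± 2.04 normalized counts (at least 9.92-fold).

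**Figure D3:**
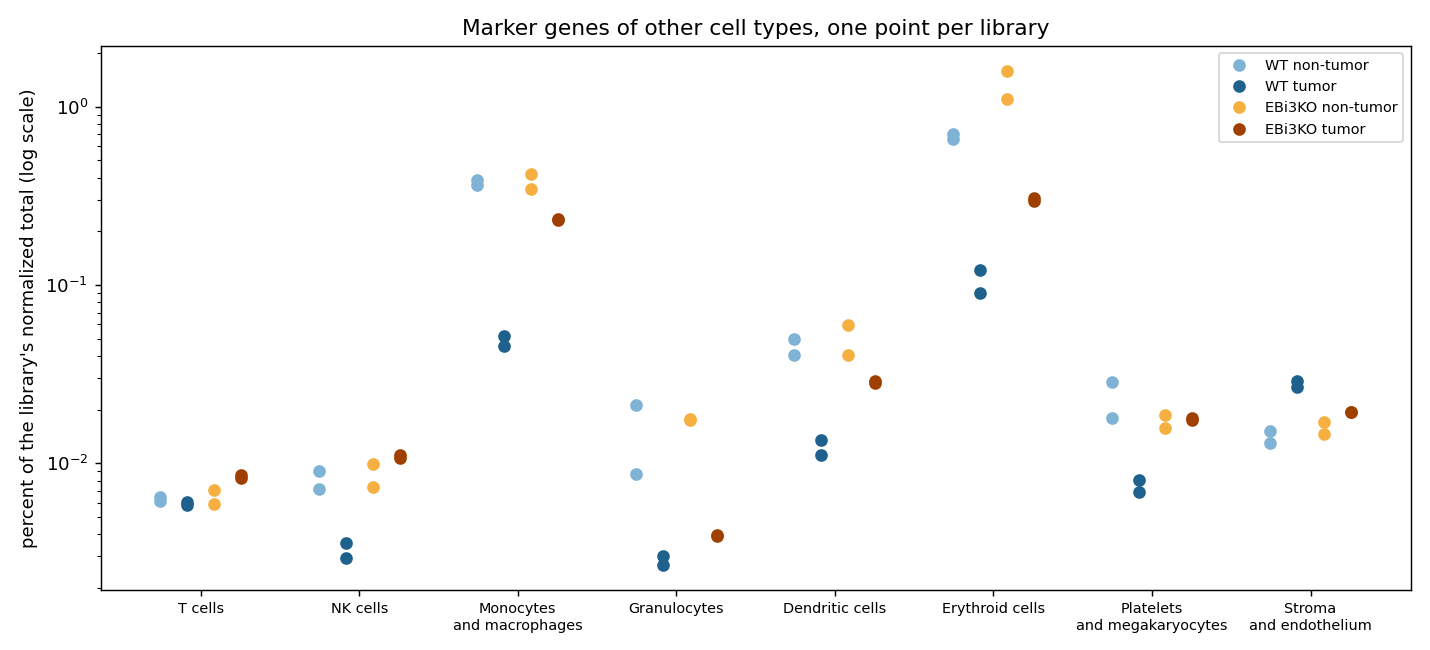
Percent of each library's reads on marker genes of other cell types, by group, with 2 libraries per group. Monocyte and macrophage markers stand at 0.0485% in WT tumor, 0.232% in EBi3KO tumor and 0.38% in EBi3KO nontumor.

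Further large rises were those of Amy2a5, a pancreatic amylase (0 reads to 280 ± 45.7 normalized counts, at least 73.2-fold), the sulfotransferase Chst1 (2.40, adjusted p = 0.00228) and the long noncoding RNA Neat1 (2.22, past in 17 of 23 alternatives). Large falls were those of Slc38a5 (-3.97) and the blood group gene Rhd (-3.90). In all 4242 genes (32.6%) were past the threshold, 1841 higher and 2401 lower, and 861 by at least 2-fold. This count was 1213 without EBi3KO nontumor replicate 2, 788 and 756 without EBi3KO tumor replicate 1 or 2, and 733 with the EBi3KO tumor libraries averaged as 1 sample. Of the 121 named genes called here 51 kept their call in every alternative. Adjusted over the list alone, counts were higher for quiescence (7 rose), the plasma cell program (9 rose, 2 fell), regulatory B cell genes (6 and 3), immediate early genes (5 and 3) and BAFF and survival (3 and 2). They were higher also for glycolysis (8 fell), oxidative phosphorylation (1 and 71), ribosomal proteins (79 fell), heat shock (8 fell), granulocytes (9 fell) and pancreas and epithelium (1 and 2), and lower for NF-kB targets (0) and T cells (1 rose).

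Set side by side, the tumor effects shared most of their direction. Of the genes called in EBi3KO, 92.6% were called the same way in WT, 1691 higher and 2237 lower where independent lists would give 729.7 and 963.5. There were 63 called in opposite directions against 1690.4 so expected. Rrm2 and Lag3 fell and Bach2 and Cd22 rose in both genotypes. Igj and Tnfrsf17 were among the 33 genes lower in WT and higher in EBi3KO. Xbp1 was too, but its fall in WT turned to 0.06 once the length and GC trend was removed, and its rise in EBi3KO ended in 4 of 23 alternatives. Across genes the log2 differences correlated (Pearson's r 0.773, Spearman's rho 0.804) with a slope of 0.349 for EBi3KO on WT, and 96.6% of the genes called in WT changed less in EBi3KO. Those genes were chosen by their change in WT, which by itself favors a smaller change in the other genotype. Over all tested genes, with no such choice, the SD of the log2 difference was 1.463 in WT and 0.66 in EBi3KO. Genes are not independent replicates. The log2 difference rose with transcript length in both tumor effects (Spearman's rho 0.358 in WT and 0.219 in EBi3KO). Such a shared trend could add to the overlap and the correlation, and by how much was not tested.

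**Figure D4:**
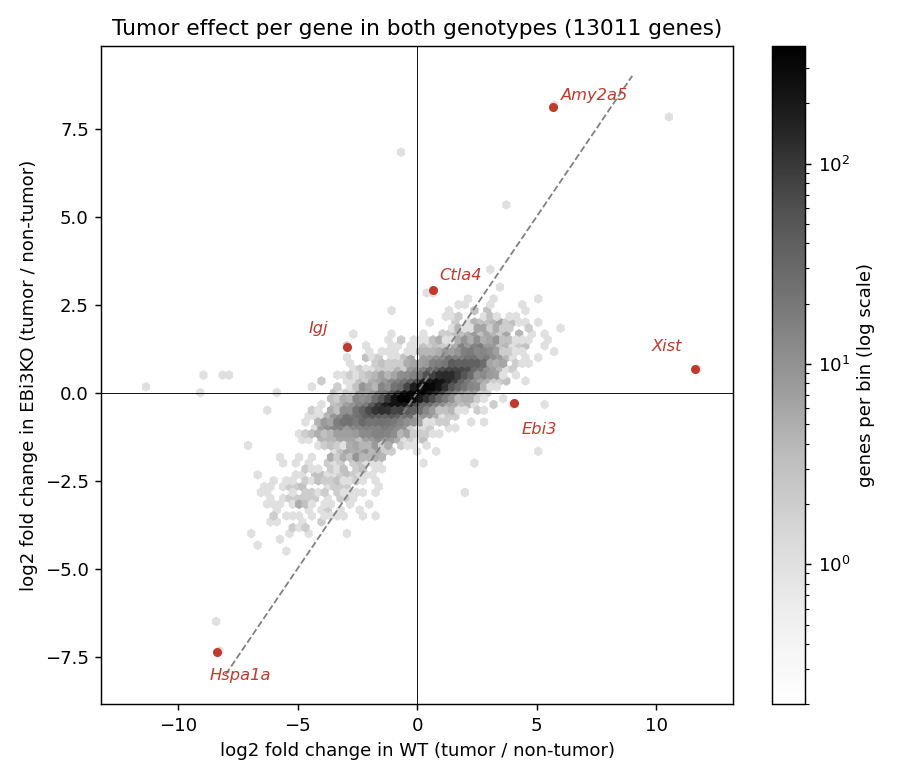
Log2 difference of tumor and nontumor in EBi3KO (vertical) against WT (horizontal) for the 13011 tested genes, shaded by the number of genes, with named genes as points. The slope over all genes is 0.349, and Igj lies at -2.92 in WT and 1.29 in EBi3KO.

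**Figure D5:**
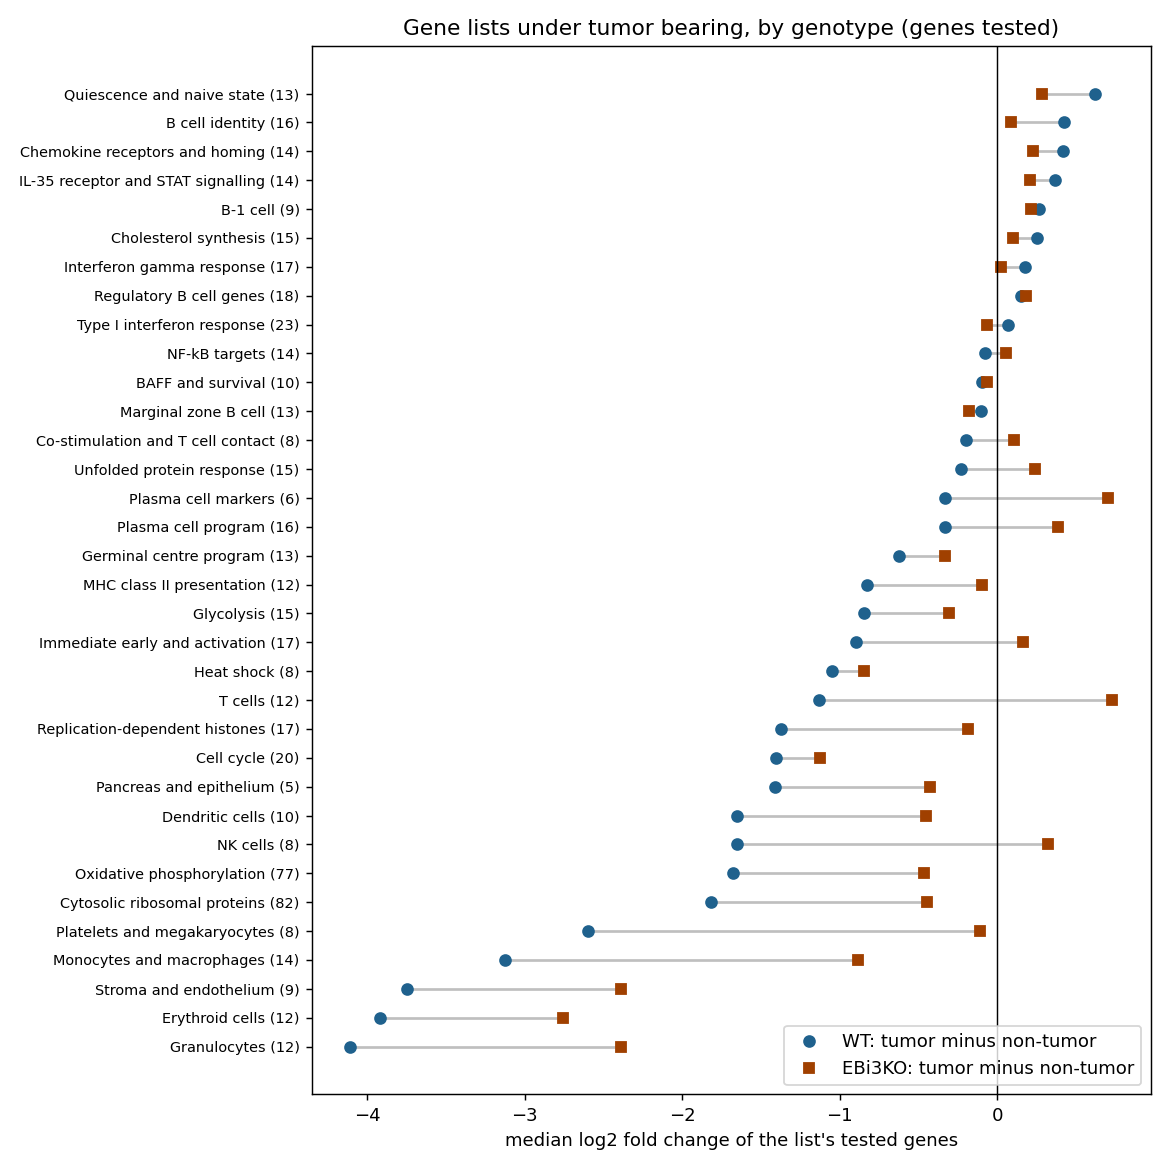
Median log2 difference of tumor and nontumor in WT (circles) and EBi3KO (squares) for each gene list with at least 5 tested members. The sex-linked list is not drawn. Plasma cell markers stand at -0.33 in WT and 0.71 in EBi3KO, and ribosomal proteins at -1.81 and -0.44.

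The genotype effect in nontumor mice asks whether B cells without Ebi3 differ before a tumor is present. Limma called 0 genes, with 1049 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 21. Genes with small p, none past the threshold, included the cytokine receptor gene Il21r (0.55, adjusted p = 0.184), Cd93 (0.86, 0.184), Rnaset2b (-0.89, 0.184) and the complement gene C4b (-1.05, 0.245). The calcium channel gene Cacna1h (1.29, 0.245), the ribosomal RNA precursor Rn45s (-1.32, 0.324), and Il4ra (0.40), S1pr3 (0.50) and Hba-a1 (0.92) at 0.36 followed. Ebi3, at 12.1 ± 0.931 in EBi3KO and 9.96 ± 1.44 in WT, lies too low in nontumor cells to tell the genotypes apart at this depth (0.26, adjusted p = 0.745). Not past the threshold either were Bcl6 (0.07, 0.731), Pax5 (0.25, 0.604), Prdm1 (-0.07, 0.877), Irf4 (0.15, 0.746), Xbp1 (-0.08, 0.739), Stat3 (-0.01, 0.956) and Il12a (0.27, 0.671).

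No list member was past the threshold over all genes. Adjusted over the list alone, 4 erythroid and 3 marginal zone genes were higher, as were 1 each of B cell identity, cell cycle and chemokine receptors. Lower were 1 each of the plasma cell program, plasma cell markers and chemokine receptors. At the preset correlation, camera called ribosomal proteins (median -0.21, adjusted p = 3.8e-20), oxidative phosphorylation (-0.16, 1.83e-12), platelets (-0.53, 3.67e-05), plasma cell markers (-0.24, 0.0243), MHC class II (-0.12, 0.0187), type I interferon (-0.12, 0.0237) and monocytes (-0.13, 0.0429) lower in EBi3KO. These lists had an adjusted p = 0.618 with an estimated correlation, and monocytes an adjusted p = 0.89. Erythroid (0.23, 0.000114) and marginal zone genes (0.12, 0.0237) were called higher, and had an adjusted p = 0.618 with an estimated correlation. B cell identity genes (0.04, 0.0976) were not called. They were past the threshold in 4 of 20 alternatives, among them removal of the length and GC trend (median 0.06, camera adjusted p = 0.021). The median of ribosomal proteins went to -0.05 and that of MHC class II to -0.01 under quantile normalization, which ended both calls. Plasma cell markers, called in 16 of 20 alternatives, stood at -0.08 among genes with a mean of at least 50. Without WT nontumor replicate 1 and 2 the median was -0.93 and -0.18 for platelets, -0.26 and -0.05 for oxidative phosphorylation and -0.23 and -0.03 for type I interferon. The median of monocytes, called in 11 of 20 alternatives, reached 0.01 without EBi3KO nontumor replicate 1. That of marginal zone genes was 0.04 without WT nontumor replicate 2, where their call and that of type I interferon ended. Chi-square per degree of freedom over genes below 10000 reads was 4.899, 8.27, 8.52 and 21.07 for the 4 pairs of nontumor libraries of different genotype, against 9.777 within EBi3KO nontumor and 10.16 within WT nontumor, a measure chosen after the values were seen.

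The genotype effect in tumor mice asks what the loss of Ebi3 changes once a tumor is present, in libraries that also differ in sex and title prefix. Ebi3 was lower in EBi3KO (9.85 ± 1.63 against 182 ± 26.4 normalized counts, n = 2 each, 16.9-fold with 1 added to each value, log2 difference -4.08, adjusted p = 2.43e-05). Igj stood at 42591 ± 203 against 3522 ± 533 (3.60, adjusted p = 8.69e-07), Tnfrsf17 at 42.9 ± 4.11 against 3.96 ± 1.14 (3.16), and Xbp1 was higher by 0.75 (0.000165), Myc by 1.27 and the cytotoxic protease Gzmb by 2.10. All 8 tested NK genes were higher as well (median 1.88), and whether Gzmb came from B cells was not tested. Bach2 (-1.46) and Ebf1, a determinant of the B lineage (-1.15), were lower. Bcl6 was lower (-0.44, adjusted p = 0.00123), until the length and GC trend was removed (-0.18), and Prdm1 higher (0.44, 0.0395, past in 15 of 23 alternatives). Pax5 (-0.08, 0.59), Irf4 (-0.06, 0.777), Stat3 (-0.08, 0.363) and Il12a (-0.44, 0.124) were not past the threshold.

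The plasma cell program (10 of 16 higher, 2 lower, median 0.68, camera adjusted p = 0.0343), plasma cell markers (5 of 6 higher, 0.72, 0.0237), immediate early genes (14 of 17 higher, 1 lower, 0.91, 0.00174) and the unfolded protein response (8 of 15 higher, 2 lower, 0.37, 0.0475, past in 12 of 20 alternatives) were higher in EBi3KO. They had an adjusted p = 0.483 with an estimated correlation, and immediate early genes an adjusted p = 0.55. The program kept its call in 17 of 20 alternatives and had a median of 0.45 after removal of the length and GC trend, where that of quiescence genes was -0.25. Mzb1 stood at 1.18, Egr2 at 1.28, Fos at 1.22 and Sdf2l1 at 1.21. Quiescence genes (9 of 13 lower, 3 higher, -0.45, 0.0419, past in 13 of 20 alternatives) and type I interferon genes (13 of 23 lower, 2 higher, -0.39, 0.0262, past in 18 of 20 alternatives) were lower, with an adjusted p = 0.556 and an adjusted p = 0.483 with an estimated correlation. Ddx58 stood at -0.90, Oasl2 at -0.86 and Foxo1 at -0.68, which turned to 0.22 after removal of the length and GC trend. MHC class II genes stood at 9 higher and 1 lower of 12 (0.05), with H2-DMa at 0.87 and Ciita at -0.77. H2-Ab1 at 0.81 and H2-Eb1 at 0.75 turned to -0.06 and -0.09 under quantile normalization, as Cd79b, of the B cell receptor, turned from 0.45 to -0.39. Identity genes stood at 3 higher and 8 lower of 16 (0.223). Their list was past the threshold in 2 of 20 alternatives, among them removal of the length and GC trend (0 higher, 7 lower, median -0.19, camera adjusted p = 0.0336). Ribosomal proteins (81 of 82 higher, median 1.13, 1.44e-22), oxidative phosphorylation (72 of 77, 1.03, 2.82e-18) and glycolysis (10 of 15, 0.48, 0.0161) were higher, with an adjusted p = 0.495, an adjusted p = 0.495 and an adjusted p = 0.55 with an estimated correlation. They stood at medians of 0.70, 0.57 and 0.12 after removal of that trend, which ended the call of glycolysis. The ribosomal median was 0.55 under quantile normalization.

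Higher too were 14 of 14 monocyte and macrophage genes (median 2.21, camera adjusted p = 3.77e-09), 8 of 8 NK genes (1.88, 0.000907), 8 of 8 platelet genes (1.76, 0.0023), and 10 of 12 T cell genes (1.37, 0.00474, median 0.895 among genes with a mean of at least 50). Their p with an estimated correlation was adjusted p = 0.483 for monocytes and macrophages, adjusted p = 0.495 for NK and T cells and adjusted p = 0.55 for platelets. So were 11 of 12 erythroid genes with 1 lower (1.46, 0.000651), 9 of 12 granulocyte genes with 1 lower (2.03, 0.0071) and 7 of 10 dendritic cell genes (0.95, 0.0475, past in 10 of 20 alternatives). These had an adjusted p = 0.483 with an estimated correlation, and granulocytes an adjusted p = 0.556. Among genes with a mean of at least 50, granulocytes and plasma cell markers were not past the threshold. C1qc stood at 3.17, Gzma at 2.36 and Car1, the red cell carbonic anhydrase, at 3.06. Beside the Y-linked genes, the largest rises included Mcpt8 (4.62) and Prss34 (4.12), proteases of basophils, Prg2, a granule protein of eosinophils (4.31), and the metallothionein Mt2 (3.61). The largest falls included Xist (-10.36), Vasn (-4.40) and the potassium channel gene Kcna3 (-3.07). In all 7866 genes (60.46%) were past the threshold, 4151 higher and 3715 lower. Across genes, which are not independent replicates, the log2 difference fell with transcript length (Spearman's rho -0.41). Adjusted over the list alone, the counts of the lists named here were the same except for ribosomal proteins (82 higher) and the unfolded protein response (9 higher). The sex-linked list (4 of 5 higher, camera adjusted p = 0.00727, but adjusted p = 0.483 with an estimated correlation) stood at a median of 8.997, or 8.35 with 3 genes at their bound.

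The interaction asks whether the tumor effect differed between the genotypes, and 6881 genes (52.89%) were past its threshold, 3579 with a more positive tumor effect in EBi3KO and 3302 with a more negative one. Ebi3 (-4.34, adjusted p = 0.000209), Ebf1 (-1.40, 0.00147), Bach2 (-1.63, 0.000117), Itga4 (-1.66, 0.000478) and Bcl6 (-0.51, 0.00458) had a lower tumor effect in EBi3KO. Bcl6 was not past the threshold once the length and GC trend was removed (-0.21). Igj (4.21, 5.13e-06), Tnfrsf17 (4.19, 0.000395), Xbp1 (0.83, 0.000976), Mzb1 (1.36, 0.00017), Cxcr4 (1.15, 0.000552), Cd69 (1.65, 0.00143), Socs3 (1.08, 0.00264) and Lag3 (2.15, 9.91e-05) had a higher one. Il12a (-0.70, 0.0936), Pax5 (-0.33, 0.155), Prdm1 (0.50, 0.0869), Irf4 (-0.22, 0.491) and Stat3 (-0.07, 0.595) were not past it. Of the genes called, 6703 had been called in WT with an interaction of opposite sign, 2544 of them with the same call in EBi3KO, 4096 with none and 63 with the opposite one. The interaction subtracts the same WT difference, so the opposite sign is partly built into this count. Leaving out chromosomes X and Y, 6669 genes were past the threshold. Across genes, which are not independent replicates, the interaction difference fell with transcript length (Spearman's rho -0.392).

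Lists with a more positive tumor effect in EBi3KO were the plasma cell program (9 of 16 up, 1 down, median 0.82, camera adjusted p = 0.0346, call ended in 5 of 20 alternatives), plasma cell markers (4 of 6, 0.96, 0.0232), immediate early genes (12 of 17, 1 down, 0.95, 0.00551), and MHC class II (9 of 12, 1 down, 0.72, 0.025). They had an adjusted p = 0.54 with an estimated correlation for both plasma cell lists and an adjusted p = 0.551 for the others. So were glycolysis (10 of 15, 0.62, 0.0266), oxidative phosphorylation (72 of 77, 1.20, 1.12e-19), ribosomal proteins (81 of 82, 1.35, 1.14e-24) and those of T, NK, monocyte, granulocyte, dendritic, erythroid and platelet markers (medians 0.94 to 2.34). These had an adjusted p = 0.54 to an adjusted p = 0.673 with an estimated correlation. Granulocytes kept their call in 11 of 20 alternatives and dendritic cells in 16, and T cells, at a median of 0.68 among genes with a mean of at least 50, lost theirs there, as did plasma cell markers. Without WT nontumor replicate 1 the granulocyte median was 1.13. Removal of the length and GC trend ended the calls of glycolysis, MHC class II (0.30), granulocyte and erythroid genes and took oxidative phosphorylation to 0.69, ribosomal proteins to 0.87 and the plasma cell program to 0.49. Under quantile normalization the median of ribosomal proteins was 0.60, that of MHC class II was 0.05 and H2-Ab1 turned from 0.93 to -0.13. Notch2, with a lower effect (-0.92), turned to 0.12 after removal of the length and GC trend. B cell identity genes were not past the threshold (median -0.28, camera adjusted p = 0.131). They were past it in 2 of 20 alternatives, among them removal of that trend (median -0.295, camera adjusted p = 0.017). Counts adjusted over the list alone were the same for the lists named with a count.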

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

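Removal of the trend on length and GC content and the tests of other cells, sex and title prefix were chosen only after the results were seen.

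The tumor effect differed between EBi3KO and WT, by the test of the interaction itself, for 6881 genes, and each value below is an interaction difference on the log2 scale past that test. Of the fixed genes these were Ebi3 (-4.34), Bcl6 (-0.51) and Xbp1 (0.83). The largest positive differences were those of Eif2s3y (11.56), Kdm5d (9.55), Uty (8.96), Ddx3y (8.30), Tmem254c (7.63, past in 8 of 22 alternatives), Nptxr (5.85), Mcpt8 (4.57), Prg2 (4.45), Sdsl (4.22) and Igj (4.21). The fitted values of Eif2s3y, Kdm5d, Uty, Sdsl and Tmem254c rest on a group with 0 reads and are no bounds. That of Nptxr rests on 0 and 1 read in the WT tumor libraries. The largest negative differences were those of Xist (-10.96), Vasn (-5.65), Il22ra1 (-4.11), 9930111J21Rik1 (-4.09), Cpt1b (-3.94, past in 9 of 22 alternatives), Zbed6 (-3.75), Kcna3 (-3.46) and Rapgefl1 (-3.42).

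The same test, over lists and at the preset correlation, was past its threshold for the plasma cell program (median 0.82), immediate early genes (0.95), MHC class II (0.72), glycolysis (0.62), oxidative phosphorylation (1.20), ribosomal proteins (1.35), sex-linked genes (8.96, or 8.30 with 3 genes at their bound), T cells (1.69), NK cells (1.92), monocytes and macrophages (2.25), granulocytes (1.78), dendritic cells (1.11), erythroid cells (0.94), platelets (2.34) and plasma cell markers (0.96). No list stayed past it, at adjusted p = 0.54 to adjusted p = 0.673 with an estimated correlation.

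The pattern behind these values is that most genes changed in WT and changed less, or were not called, in EBi3KO. Choosing genes by their call in WT favors this pattern. Over all tested genes the SD of the log2 difference was 1.463 in WT and 0.66 in EBi3KO. Against transcript length as the whole cause, 9799 genes were past the threshold in WT after the length and GC trend had been removed, although 373 of the 8596 genes called in both fits turned direction. Of the genes called higher, 52.5% rose by 2-fold or more, where markers of other cells hold only a few percent of the reads. The share of RNA that came from those cells was not measured, so this cannot decide whether fewer other cells caused the rises. Against sex or title prefix as the cause of the direction shared by genes called in both genotypes, such genes were 2.32 times as many as independent lists would give, and the EBi3KO libraries share 1 sex and prefix. This covers the direction and not the size of the changes. Both tumor effects rose with transcript length (rho 0.358 in WT and 0.219 in EBi3KO), which could add to the number of genes called the same way in both genotypes. Of these genes 2544 changed more in WT by the test of the interaction, and for that excess sex and title prefix cannot be told apart from the tumor or the loss of Ebi3. A part of the changes may still follow transcript length (rho 0.358, with -0.262 and 0.274 between replicates of the WT groups), and the weaker rank correlation with GC content (-0.181) decided nothing. For the 6387 genes called in WT alone, sex and title prefix cannot be told apart from the tumor or from the loss of Ebi3, since no WT tumor library is male or carries the other prefix, and the biological explanation that Ebi3 in B cells shapes the response to the tumor stays open and untested.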

How the results depend on the processing

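The removal of the length and GC trend, the averaging of the EBi3KO tumor libraries and the fits without chromosomes X and Y were added after the data had been seen. The counts of the tumor effect in WT (9024 to 11554), the genotype effect in tumor mice (5526 to 9613) and the interaction stayed within 1.5 times their value under every alternative run. The tumor effect in EBi3KO called 4242 genes, but 2375 when moderated without a trend and 733 with the EBi3KO tumor libraries averaged, a fit with fewer samples. The genotype effect in nontumor mice called 0 genes, and 21 with DESeq2, for which the cause was not tested. With each library left out in turn the counts ran from 9170 to 10603 for the tumor effect in WT, 756 to 5313 for that in EBi3KO, 0 to 5 for the genotype effect in nontumor mice, 5526 to 8321 for that in tumor mice and 4944 to 7495 for the interaction, where the library left alone in its group was assumed to vary like the others. The 5 genes were called without EBi3KO nontumor replicate 2. With the title number as a replicate block, the tumor effect in WT called 9305 genes. Nothing says that the shared numbers mark the same animals, and across genes the deviations of libraries with the same number correlated negatively (Pearson's r -0.256, Spearman's rho -0.414).

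Among the named genes, called directions reversed in 13 cases, and the cause was not tested. Under quantile normalization these were Hspa8 in the tumor effect in WT (0.63), Cd79b (-0.39), H2-Ab1 (-0.062) and H2-Eb1 (-0.091) in the genotype effect in tumor mice, and H2-Ab1 in the interaction (-0.13). After removal of the length and GC trend they were Xbp1 (0.055), Stat3 (-0.018), Foxo1 (-0.41), Notch2 (-0.28), Cd40 (0.037) and Sel1l (-0.081) in the tumor effect in WT, Foxo1 in the genotype effect in tumor mice (0.22) and Notch2 in the interaction (0.12). Of the named genes called, 138 of 151 kept their call in every alternative in the tumor effect in WT, 51 of 121 in that in EBi3KO, 112 of 141 in the genotype effect in tumor mice and 113 of 133 in the interaction. With a correlation estimated per list, 69 list calls ended. Robust moderation was not run for the lists, a fit of the compared libraries alone was not run for the interaction or the lists, and an alternative on immunoglobulin genes was not run because the table holds none. Depth limits genes near the floor, such as Ebi3 in nontumor cells.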

Other observations

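The set of acinar genes, the averaging of the EBi3KO tumor libraries, and the test of 1 RNA sample were chosen only after the values were seen.

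Transcripts of digestive enzymes of the exocrine pancreas were found in the tumor libraries. Of 27 such genes looked up, a set of which only Pnlip, Prss2, Cpa1, Cela1 and Ctrb1 had been listed before, 12 had 0 reads in all 4 nontumor libraries and a read in all 4 tumor libraries. A further 6 had a read in every nontumor library and 2 (Prss1 and Prss3) had none anywhere. The amylase gene Amy2a5 had 0 reads in nontumor, 626 in EBi3KO tumor and 129 in WT tumor, Pnlip 0, 85 and 31, the carboxypeptidase gene Cpb1 0, 63 and 14, and the elastase gene Cela2a 0, 63 and 15. Cela1, which nontumor libraries express, had 5187, 1477 and 194 reads. These totals cover 4 nontumor libraries but only 2 libraries of each tumor group. Per library, Cela1 had 1048 to 1480 reads in nontumor, 752 and 725 in EBi3KO tumor, and 112 and 82 in WT tumor. Without Amy2a5 and Cela1 the set summed to 42 and 58 reads in EBi3KO nontumor, 45 and 38 in WT nontumor, 326 and 353 in EBi3KO tumor, and 240 and 252 in WT tumor. These sums include Amy2a4 (44 reads in EBi3KO tumor, 174 in WT tumor) and Ctrl (69 and 116), which had reads in every nontumor library. Both were higher in WT tumor, unlike Pnlip, Cpb1 and Cela2a.

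Some abundant transcripts differed widely between libraries. The ribosomal RNA precursor Rn45s stood at 210540 ± 8379 normalized counts in WT nontumor, 85370 ± 20950 in EBi3KO nontumor, 43682 ± 8591 in WT tumor and 99050 ± 23080 in EBi3KO tumor, and the heat shock gene Hspa1b at 17378 ± 5181, 34099 ± 35690, 53.7 ± 0.363 and 263 ± 18.6. Mki67, a proliferation marker, had a lower tumor effect in EBi3KO than in WT, unlike the other cell cycle genes past that test (interaction -1.96, adjusted p = 0.000209). It stood at 479 ± 26.8 in WT nontumor and 1402 ± 170 in WT tumor, and at 760 ± 140 and 566 ± 21.6 in EBi3KO.

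The EBi3KO tumor libraries were closer to each other than any other replicates. Their chi-square per degree of freedom over genes below 10000 reads was 1.446, where the lowest of the other replicate pairs was 5.35, and over all genes it was 2.014 against 20.3 in EBi3KO nontumor, 16.05 in WT nontumor and 13.14 in WT tumor. A candidate explanation is 1 RNA sample prepared or sequenced more than once, and no biological explanation was tested. If that holds, the genotype effect in tumor mice and the interaction also rest on 1 sample in this group, and their p-values are too small. The p-values of the tumor effect in WT and the genotype effect in nontumor mice would be too small as well. All groups share a spread that was estimated partly from these 2 libraries. They were kept as 2 libraries, and averaged as 1 sample the tumor effect in EBi3KO called 733 genes in place of 4242.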
